A study of Pseudarthrobacter chlorophenolicus A6 with 16 samples.

How the data were processed

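Transcript levels of the soil bacterium Arthrobacter chlorophenolicus were measured on 16 one-colour Agilent arrays, 4 for each of 4 treatments. Per the labels' protocols, cells were dipped onto bean leaves or spread on dilute tryptone soy agar, total RNA was extracted after 2 days, and Cy3-labelled cDNA was made with random primers. The labels state that the 4 replicates of a treatment were prepared independently. Per the file headers, the arrays were scanned in 1 colour and the spots were read with Agilent Feature Extraction 10.5.1.1, which subtracted the background and detrended the signals. The deposited scanner files give each spot's processed intensity on a linear scale, not normalised between arrays, with flags for signal well above background, outliers and saturation.

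The authors also deposited a table of log2 values, 1 per locus tag and sample, whose making is not given in the sources used here. Its 4625 rows were recomputed from the scanner files as the mean log2 processed intensity of a tag's probes, quantile normalised between arrays and centred on each tag's median. The recomputed values differed from the deposited log2 values by a median of 0.00109, which settled their scale, centring and direction. The medians of the table's columns lay between -0.06 and 0.06.

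Each array held 14125 spots, of which 13582 were probes for 4625 locus tags (3 probes for 4400 of them), and 7 were probes for introduced reporters. The main values were the log2 processed intensity minus the array's 75th percentile over the locus-tag probes. A probe was kept if it was well above background on at least 3 of the 4 arrays of at least 1 treatment. The 155 probes with an outlier flag on any array were left out on all arrays, and no spot was saturated. This handling was chosen after the data were seen: the first version set single outlier spots missing, which inflated the error of a gene whose probes differ in level, and its counts are given among the alternatives. The mean over a tag's remaining 13078 probes gave values for 4609 tags, called genes below. Below, a gene counts as well above background on an array if at least 1 of its tag's probes was, including probes left out. A gene that passes on every array may therefore still hold dim probes. The number of arrays limits the precision of every value.

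Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 16 arrays in 1 model of 4 groups, so that each gene had 1 estimate of its spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, the tests, the alternatives and a rule for naming genes were fixed. The rule took, from the called genes whose 4 values in 1 group all lay above the 4 in the other, the 8 largest rises and 8 largest falls per comparison, or 5 each way for the comparison of leaves with chlorophenol. The files do not pair the locus tags with gene names or products, so the rule ran over all genes and the text names the first 2 each way. For the same reason 29 gene lists defined by product names could not be tested.

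Runs of locus tags were described in their place, by a definition chosen after the data were seen. A run was 3 or more consecutively numbered tags that were all called and all changed at least 2-fold in 1 direction. Each number of tags in runs was set beside 1000 shuffles of the changes over the tags. Tag numbers were used as an order only, and no genome coordinates were used.

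All 8 leaf arrays lay on slide 1 and were scanned together, and all 8 agar arrays lay on slide 2 with a scan of their own. Slide and growth surface therefore cannot be told apart in any comparison of leaves with agar. The 2 humidities shared slide 1, and the 2 agar treatments shared slide 2, where plain agar filled 1 column and chlorophenol agar the other. Replicate numbers were checked for pairing through the correlation of deviations from the group means. For the 2 agar treatments, every pair with the same number correlated above 0.1, from 0.22 to 0.35, and the same numbers also shared a row of the slide. For the leaf treatments with each other and with agar, at least 1 pair of each set fell below 0.1.

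The steps were tested on simulated data, in which 200 of 4609 genes were changed in values drawn with each group's own spread. For the high humidity leaves against agar, 58.0% of changes of 1 log2 unit and 91.0% of changes of 2 log2 units were recovered, and 11.8% of the calls were false. The false share was 16.8% for low humidity leaves against agar and 17.5% for high humidity leaves against chlorophenol agar. For chlorophenol agar against agar the fit recovered 48.0% and 96.0%, with 1.37% false calls. For low against high humidity leaves it recovered 66.0% and 94.0%, but 26.9% of the calls were false. A fit of the 8 leaf arrays alone recovered 28.0% and 80.0%, with 3.57% false calls. The real lists held 7.57% of the genes for low against high humidity leaves and 44.2% to 61.0% in the other comparisons. Recovery and false share depend on the share of genes changed, so the simulated rates do not describe the real lists. The run definition found the 1 planted run of 8 tags.

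Alternatives covered the scaling, background correction, filter on dim probes, summary over probes, arrays in the fit, moderation, a 2-fold threshold, a replicate block, the deposited table and leaving out each replicate. The planned background correction with normexp (offset 50) used median signals, because the scanner files used here hold no mean signals. Array weights, keeping the outlier probes, setting single outlier spots missing, slide column as a block, and leaving out genes whose probes disagreed were added after the data were seen.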

Results

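The study asked which transcripts of Arthrobacter chlorophenolicus, a soil bacterium that grows on 4-chlorophenol, differ between leaf surfaces and agar, how humidity affects them on leaves, and how they respond to the pollutant. Cells were kept for 2 days on bean leaves at 97% relative humidity (high humidity leaves), or for 1 day each at 97% and then 50% (low humidity leaves). Other cells were kept at 97% humidity on agar without or with 1 mM 4-chlorophenol. Each treatment had 4 arrays. The 75th percentile of the processed intensity was 529 to 570 on the high humidity leaf arrays, 439.9 to 650 on the low humidity leaf arrays, 618 to 822 on agar and 1581 to 2328 on chlorophenol agar. Between 83.8% and 98.3% of the probes of an array were well above background. Levels below are log2 signals relative to the array's 75th percentile, given as mean ± SD.

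The first principal component of the 4609 genes held 48.4% of the variance and separated the leaf arrays from both agar treatments. It also set the agar arrays (15.2 to 26.6) apart from the chlorophenol agar arrays (48.2 to 54.2). The second, with 23.03%, separated the agar treatments from each other too, and the 2 leaf humidities overlapped on both components. Replicates correlated at 0.88 to 0.96 on high humidity leaves, 0.90 to 0.95 on low humidity leaves, 0.97 to 0.98 on agar and 0.98 to 0.99 on chlorophenol agar. The median SD of a gene between replicates was 0.38 and 0.39 on the 2 leaf treatments, against 0.22 on agar and 0.20 on chlorophenol agar.

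**Figure D1:**
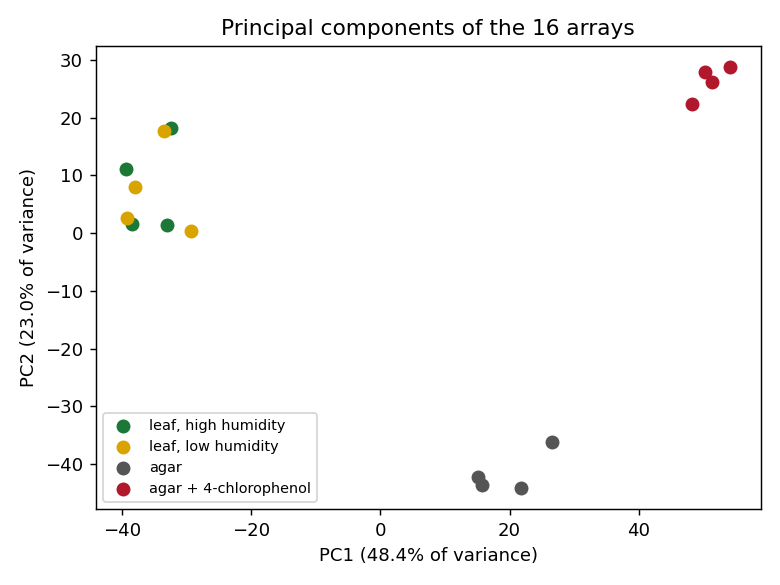
Each point is 1 of the 16 arrays, placed by the first (48.4% of the variance) and second (23.03%) principal components of the normalised log2 values of all genes and coloured by treatment. The leaf arrays lie apart from both agar treatments on the first axis, and the 2 humidities overlap.

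On high humidity leaves, compared with agar at the same humidity, the largest rises were in Achl_3864 and Achl_0362. Achl_3864 rose 94.9-fold (log2 change 6.57, SE 1.15, adjusted p = 0.000239), from -5.27 ± 0.21 on agar to 1.29 ± 2.45 on leaves (n = 4 each), so its leaf replicates varied widely. Achl_0362 rose 93.1-fold (log2 change 6.54, SE 0.48, adjusted p = 5.97e-08), from -3.36 ± 0.36 to 3.19 ± 0.92, and was the strongest of a run of 4 consecutive tags with a mean log2 change of 3.98. The largest falls were in Achl_0177, 30.6-fold lower on leaves (log2 change -4.94, SE 0.39, adjusted p = 9.62e-08), and Achl_4451, 24.05-fold lower (log2 change -4.59, SE 0.27, adjusted p = 6.01e-09). Over the alternatives in processing, the log2 change of Achl_4451 ranged from -4.92 to -2.45. Achl_0177 was part of a run of 6 tags that all fell, by a mean log2 change of -2.65. The longest fallen run held 11 tags with a mean log2 change of -2.96, and the longest risen run held 10 tags with a mean of 2.25. In all, 58 risen and 31 fallen runs took in 347 tags, against at most 96 in any of 1000 shuffles.

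Of 4609 genes, 2197 were called between high humidity leaves and agar, 981 higher and 1216 lower on leaves, and 1189 of them changed at least 2-fold. Changes of at least 8-fold were mostly rises, with 99 genes higher and 19 lower. Among genes with at least 3 probes that rose at least 2-fold, 100 of 539 had a probe that moved the other way, against 8 of 448 that fell. The control probe eQC-40, which belongs to no gene of the bacterium, gave 2240 to 7202 intensity units on these leaf arrays and 3.72 to 4.64 on agar. Under normexp background correction 1371 genes were called, 903 higher and 468 lower, which turned the balance of rises and falls. Slide and scan cannot be told apart from the growth surface here.

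On low humidity leaves, compared with agar kept at high humidity, Achl_2643 and Achl_4300 rose the most. Achl_2643 was 202-fold higher (log2 change 7.66, SE 0.53, adjusted p = 1.98e-08), at 4.08 ± 0.39 against -3.58 ± 0.31 on agar (n = 4 each). It led a run of 8 tags with a mean log2 change of 4.41; the mean of the same tags on high humidity leaves was 1.99. Achl_4300 was 171-fold higher (log2 change 7.42, SE 1.02, adjusted p = 2.38e-05). Its value rests on the 1 probe that passed the filters, so agreement between probes could not be checked. At least 1 of the tag's probes was well above background on 3 of the 4 agar arrays. The log2 change of Achl_4300 ranged from 2.32 to 8.28 over the alternatives in processing. The largest falls were 32.1-fold in Achl_4451 (SE 0.27 on the log2 scale, adjusted p = 2.91e-09) and 30.1-fold in Achl_1617 (log2 change -4.91, SE 0.48, adjusted p = 6.77e-07). For Achl_4451 the log2 change ranged from -5.19 to -2.41 over the alternatives. Achl_1617 lay in a run of 5 tags that fell together, by a mean log2 change of -3.44. The 11-tag run that fell on high humidity leaves fell here too, by a mean of -3.11, and the 10-tag run that rose there rose by a mean of 2.51, each with every tag called.

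In this comparison 2035 genes were called, 875 higher and 1160 lower on leaves, with 1102 changed at least 2-fold, and 303 tags lay in runs (at most 80 in shuffles). Substrate and humidity differ together here. The 2 leaf treatments shared 1600 genes called in the same direction against agar, 708 higher and 892 lower, and 6 called in opposite directions. Independent lists of the same lengths would share 492. Unchanged groups simulated against shared agar arrays shared at most 1, but they hold almost no calls to share. With the agar arrays split into pairs, so that none served both comparisons, 1063 to 1129 genes were shared, against 272 to 286 for independent lists of those lengths. The fold changes of the 2 leaf treatments correlated across genes at r = 0.88 (genes are not independent replicates), with a covariance of 1.11 against a simulated 0.03. Of the genes that rose at least 2-fold and had at least 3 probes, 90 of 472 had a probe that moved the other way. The eQC-40 probe gave 501 to 2904 on these leaf arrays. Under normexp 1354 genes were called, 930 higher and 424 lower, and as at high humidity slide and surface cannot be told apart.

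**Figure D2:**
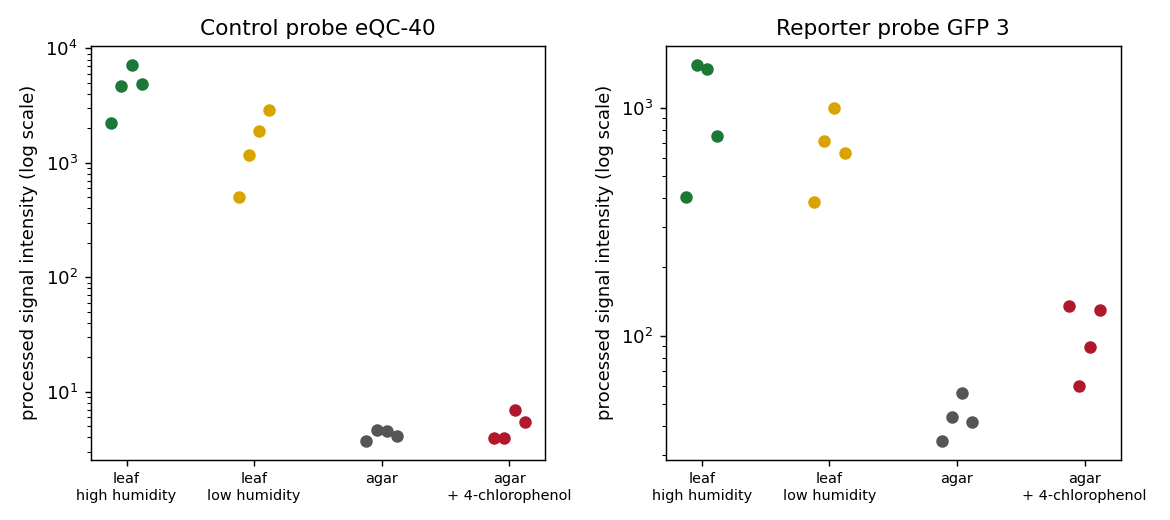
Processed signal intensity (log scale) of the control probe eQC-40 and of 1 of 3 reporter probes for green fluorescent protein, with 1 point per array and 4 arrays per treatment. Every leaf array lies above every agar array for both probes, at 501 to 7202 for eQC-40 and at 387 to 1543 for the reporter probe.

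Between the humidities, the longest run held 9 consecutive tags, among them Achl_3262. It was lower on low than on high humidity leaves, by a mean log2 difference of -2.69. Achl_3262 itself was 18.5-fold lower (log2 change -4.21, SE 0.27, adjusted p = 1.80e-07), at -1.73 ± 0.18 against 2.49 ± 0.73 (n = 4 each), with agar at -3.29 ± 0.13. The run's mean log2 change from agar was 3.93 on high humidity leaves and 1.24 on low humidity leaves. Achl_2928 was 10.6-fold lower at low humidity (log2 change -3.41, SE 0.34, adjusted p = 1.34e-05). The size is uncertain, because it was well above background on 3 of the 4 low humidity arrays. Higher at low humidity were Achl_2650 (fitted log2 change 3.85, SE 0.43, adjusted p = 5.26e-05), whose size is uncertain because it was well above background on only 2 of 4 high humidity arrays, and Achl_4566, by 11.05-fold (log2 change 3.47, SE 0.30, adjusted p = 3.87e-06). Achl_4566 stood in a run of 4 tags, and its level of 3.05 ± 0.41 on low humidity leaves compared with 2.97 ± 0.38 on chlorophenol agar, -0.41 ± 0.48 on high humidity leaves and -2.45 ± 0.53 on agar. Under normexp the calls of Achl_2650 (log2 change 1.45, adjusted p = 0.141) and Achl_2928 (log2 change -1.13, adjusted p = 0.273) were lost.

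**Figure D3:**
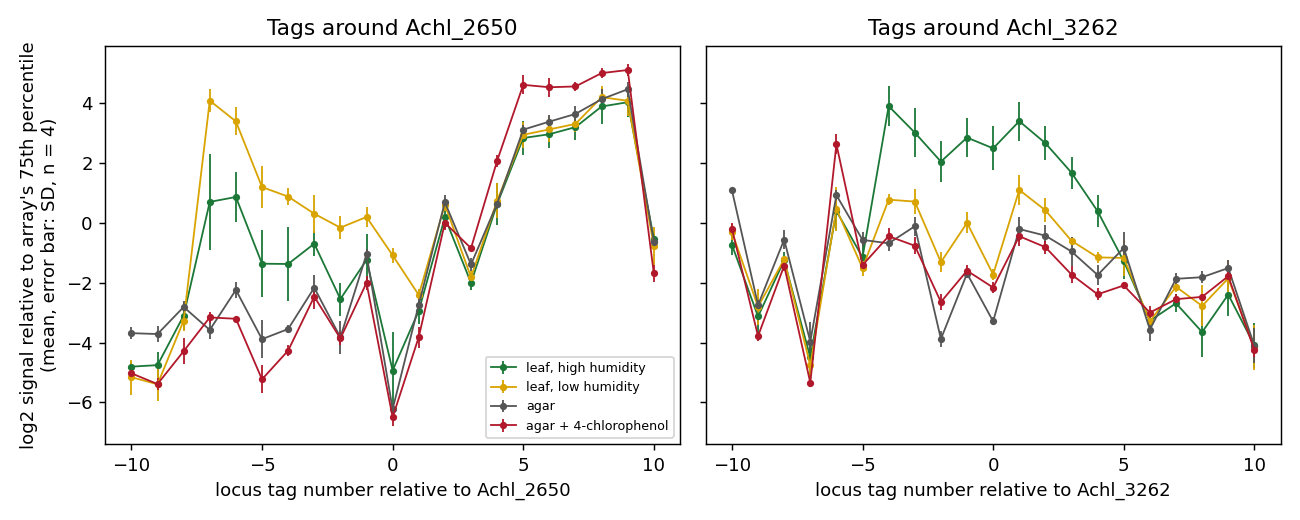
Mean log2 signal relative to the array's 75th percentile (error bars SD, n = 4) for consecutive locus tags around Achl_2650 and Achl_3262 in the 4 treatments. The run of 9 tags around Achl_3262 is highest on high humidity leaves, and the tags just before Achl_2650 have their highest means on low humidity leaves, where the leaf arrays alone called 2 of the 3 tags of its run and 2 of the 4 of the run led by Achl_2643.

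The 16-array fit called 349 genes between the humidities, 196 higher and 153 lower at low humidity, and 57 tags lay in runs (at most 4 in shuffles). The leaf replicates varied more than the agar replicates that share this estimate of the spread. Within the slide that holds both humidities, the 8 leaf arrays alone gave 69 genes, all among the 349, which included all 9 tags of the Achl_3262 run and all 4 of the Achl_4566 run, but 2 of the 3 tags of the run holding Achl_2650 and 2 of the 4 of a run led by Achl_2643. With slide column as a block the leaf arrays gave 88 genes. Under normexp 42 genes were called. Without high humidity replicate 4 the 16-array fit called 223 genes, and without low humidity replicate 4 it called 231.

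With 4-chlorophenol in the agar, 2 nearby stretches of consecutive tags rose. Achl_4572 rose 193-fold over agar (log2 change 7.59, SE 0.33, adjusted p = 1.47e-10), from -1.72 ± 0.69 to 5.88 ± 0.20 (n = 4 each), in a run of 3 tags with a mean log2 change of 6.19. Achl_4568 rose 99.7-fold (log2 change 6.64, SE 0.28, adjusted p = 1.27e-10), in a run of 7 tags with a mean of 5.12. On leaves, Achl_4572 had log2 changes from agar of -0.62 (high humidity, adjusted p = 0.132) and -0.13 (low humidity, adjusted p = 0.771). Achl_4568 had -0.19 and -0.23 (adjusted p = 0.5996 and 0.527). Other tags of these runs were lower on leaves than on agar. Achl_4570 had log2 changes of -1.16 and -1.29 (adjusted p = 0.00502 and 0.00269). The tag just before Achl_4570 and the tag just after Achl_4572 were also called lower at both humidities. Achl_4574 was called at neither. The 7-tag run also held the 4-tag run of Achl_4566, which did rise on leaves. Its mean log2 change from agar was 1.62 on high and 4.45 on low humidity leaves. The largest falls were in the adjacent tags Achl_0711, 264-fold lower with chlorophenol (log2 change -8.04, SE 0.39, adjusted p = 4.57e-10), and Achl_0710, 129-fold lower (log2 change -7.01, SE 0.34, adjusted p = 4.57e-10). Achl_0711 went from 5.28 ± 0.82 on agar to -2.76 ± 0.60. The longest risen run held 20 tags with a mean log2 change of 1.32, and the longest fallen run 10 tags with a mean of -1.68.

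**Figure D4:**
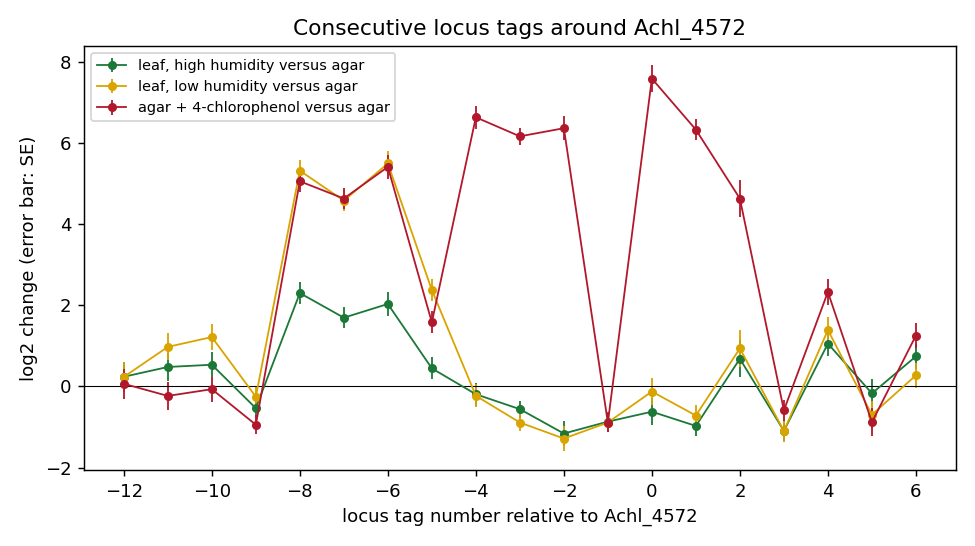
Log2 change from agar (error bars SE) of consecutive locus tags around Achl_4572 for the 2 leaf treatments and for chlorophenol agar. Achl_4572 and Achl_4568 (log2 changes 7.59 and 6.64) rise with chlorophenol and were not called on leaves. Achl_4570 rises with chlorophenol and is lower on both leaf treatments, while Achl_4566 rises in all 3 treatments.

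Between chlorophenol agar and agar 2484 of 4609 genes were called, with 1080 higher and 1404 lower, and 1380 changed at least 2-fold. Tags in runs numbered 487, against at most 141 in shuffles. Both treatments lay on the same slide, and their 8 arrays alone gave 3071 genes. The chlorophenol arrays were brighter than the agar arrays, by 1.45 log2 units at the 75th percentile (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows), and the treatments filled different slide columns. Under normexp 641 genes were higher and 1292 lower, and under quantile normalization 1198 were higher and 1137 lower, so the balance of rises and falls was not settled.

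Compared directly, high humidity leaves and chlorophenol agar differed most in Achl_0710 and Achl_0711, which were 1229-fold and 1140.0-fold higher on leaves (log2 change 10.26, SE 0.34, adjusted p = 3.18e-12, and 10.15, SE 0.39, adjusted p = 2.00e-11). Both genes had also risen on high humidity leaves over plain agar, by log2 changes of 3.25 and 2.11 (adjusted p = 1.61e-06 and 0.000388). Lower on leaves were Achl_4572, by 298-fold (log2 change -8.22, SE 0.33, adjusted p = 2.48e-11), and Achl_4570, by 185-fold (log2 change -7.53, SE 0.30, adjusted p = 2.48e-11). The 20-tag run that rose with chlorophenol was lower on leaves in this comparison, with all 20 tags called and a mean log2 difference of -1.30. A run of 10 tags was higher on leaves by a mean of 3.02.

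This comparison called 2810 genes, 1447 higher and 1363 lower on leaves, and 769 tags lay in runs (at most 263 in shuffles). The deposited log2 table gave 1075 higher and 1565 lower, and normexp gave 2288 higher and 725 lower, so the balance of directions was not settled. The 2 groups lay on different slides.

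High humidity leaves and chlorophenol changed 943 genes in the same direction relative to agar, 295 higher and 648 lower, and 307 in opposite directions. Independent lists would share 230 higher and 370.4 lower genes. Unchanged groups simulated against shared agar arrays gave at most 1 shared gene, again with almost no calls to share. Splitting the agar arrays into pairs gave 589 to 678 shared genes, against 332 to 387 for independent lists of those lengths. A shift common to all agar arrays would enter both comparisons in every such split. Fold changes correlated across genes at r = 0.30, below the 0.38 of the simulation, while their covariance was 0.36 against a simulated 0.03. The 11-tag run that fell on both leaf treatments also fell with chlorophenol, by a mean log2 change of -1.55 with all 11 tags called. Under normexp 401 genes were shared.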

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

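The tests of patterns in this part were chosen after the results were seen; the splits of the 16 arrays were planned before, while those of the leaf arrays alone, those that part replicate numbers, and the humidity differences on the leaf arrays alone were not.

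On leaves, 2 probes outside the comparisons lit up. The control probe eQC-40 was higher by 9.06 log2 units on the 8 leaf arrays than on the 8 agar arrays, and 1 of 3 probes for green fluorescent protein by 3.56 log2 units (exact permutation tests, two-sided, p = 0.000155 for each, the smallest they can give). The other green fluorescent protein probes stayed between 3.30 and 59.2 on all arrays. Of 60 control probes, eQC-40 was the 1 that was at least 2-fold higher on average and higher on every leaf array than on any agar array.

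Together with this, 18.6% of the genes that rose at least 2-fold on high humidity leaves had a probe moving the other way, against 6.84% of those raised by chlorophenol (Fisher's exact p = 1.12e-08) and 1.79% of those that fell on leaves (p = 1.0004e-19; genes are not independent replicates). Noise of the leaf arrays would show as much between the humidities, where the share was 1.15% (1 of 87 genes). Both humidities lay on slide 1, so an effect of that slide on single gene probes would cancel there. Such an effect stays open. The sets of genes whose shares are compared here were not matched on signal level. On high humidity leaves the median log2 change from agar was 0.21 in the lowest of 5 level bins and -0.28 in the highest. With chlorophenol it was -0.37 in the lowest and 0.03 in the highest. Signal level therefore also stays open as a cause of the differences between these shares. A factor common to all probes of a slide would raise other control probes too, and the 18 others above 5 log2 units on agar differed by a median of -0.21 (SD 0.68), the highest being the corner control GE_BrightCorner at 2.46. A candidate explanation is nucleic acid other than the bacterium's own in the leaf washes, binding single probes; its origin was not tested. For eQC-40 a control RNA added to the leaf samples, or another effect of the leaf slide on single control probes, also stays open, although 3 other eQC probes were lower on leaves, by -1.25 to -0.29 log2 units.

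Many genes differed between leaves and agar, and 0 slides hold both, so slide or scan cannot be told apart from the surface for these counts. Independent errors of single probes between slides would leave neighbouring tags unrelated. Their changes on high humidity leaves correlated at 0.37 across 4571 neighbouring pairs, against at most 0.04 in 1000 shuffles, which argues against such errors as the whole cause. Effects of handling that act on whole transcripts, and the growth surface itself, stay open.

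Other splits of the arrays bear on chance. They mix the treatments compared, so a large difference between treatments enters the spread and lowers the calls. The counts of these other splits therefore do not measure how many genes chance alone would call. For high humidity leaves against agar, the real grouping was the 1 of 35 splits that reached 2197 genes, and the highest other gave 1. For low humidity leaves it was 1 of 35, with 2035 genes against 1, for chlorophenol 1 of 35, with 2484 against 0, and for leaves against chlorophenol 1 of 35, with 2810 against 1. For the 943 genes changed in the same direction by leaves and chlorophenol, it was 1 of 100 splits drawn, with 0 the highest other; regrouped arrays call almost no genes to share, so this split bears on the calls and not on their sharing. Between the humidities the real split was again 1 of 35, but with 349 genes against 342 for the split that exchanges high humidity replicate 1 and low humidity replicate 2. The split by slide column gave 160. On the leaf arrays alone the real split gave 69 genes, the exchanged split 24 and the column split 9. Chance is excluded at 0.05 for the counts of called genes only as far as the arrays are freely exchangeable. Agar and chlorophenol arrays with the same number were correlated, and 8 splits part all 4 of their pairs, too few for a share under 0.05; the real one gave 2484 genes and the highest other 0. Leaf arrays of the 2 humidities correlated at 0.54 for replicates 1 and 0.60 for replicates 2, but at 0.11 and -0.01 for replicates 3 and 4. Replicates 1 shared a slide column, as did replicates 2, while replicates 3 and replicates 4 did not. The split with 342 genes sets both replicates 1 against both replicates 2, and 3 of the 4 arrays on each of its sides also share a slide column. Of the crossed pairs in the same column, high humidity 3 with low humidity 4 and high humidity 4 with low humidity 3 correlated at 0.38 and 0.32. The other such pairs correlated less. High humidity 1 with low humidity 4 gave 0.14, and high humidity 4 with low humidity 2 gave -0.02. High humidity 2 with low humidity 3 and high humidity 3 with low humidity 1 gave -0.18 each. All crossed pairs in different columns correlated negatively, from -0.48 to -0.11. Replicate number and slide column were not separated by any test as the source of this structure. Among the 8 splits that part all 4 numbers the real one gave 349 genes and the highest other 0, again too few splits for a share under 0.05.

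Of the genes named in the comparisons of leaves with agar, 3 had a called difference between the humidities in the 16-array fit. The change from agar was higher at low than at high humidity by 1.46 for Achl_0177 (adjusted p = 0.0301) and by 3.38 for Achl_2643 (adjusted p = 0.00102), and lower, at -1.68, for Achl_1617 (adjusted p = 0.0417). On the leaf arrays alone the call held for Achl_2643 (adjusted p = 0.038) and was lost for Achl_0177 (adjusted p = 0.2005) and Achl_1617 (adjusted p = 0.257), whose values at the 2 humidities overlapped. Their SEs rose from 0.39 to 0.48 and from 0.48 to 0.61 without the agar arrays.

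Single arrays lay far from their group in 5 of 52 groups of values examined, where chance gives about 1 in 20. Agar replicate 3 had 94.4% of probes well above background, against 91.2% to 91.7% on the other agar arrays. Achl_0177 was at 0.98 in high humidity replicate 3 (others -0.71 to -0.46), and Achl_4451 at -4.71 in high humidity replicate 2 (others -4.02 to -3.92). Achl_0711 was at 8.15 in high humidity replicate 4 (others 7.09 to 7.17). Achl_4300 was at -5.35 in agar replicate 4 (others -3.44 to -3.40).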

How the results depend on the processing

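Normexp on median signals, array weights, the slide column block, both other treatments of outlier probes, and leaving out genes with disagreeing probes were chosen after the data were seen. Normexp moved 4 counts by over 1.5 times, to 1371 for high humidity leaves against agar, 1354 for low humidity leaves, 42 between the humidities and 401 for genes shared by leaves and chlorophenol. It also moved the median log2 change of all genes, from -0.08 to 0.36 for high humidity leaves, from -0.13 to 0.43 for low humidity leaves from -0.15 to -0.43 for chlorophenol and from 0.08 to 0.75 for leaves against chlorophenol; the cause was not tested. Quantile normalization moved the last 2 medians to -0.02 and -0.13, median scaling to -0.05 and -0.04, and the deposited table to -0.01 and -0.15. A 2-fold threshold, which is stricter by construction, gave 1189, 1102, 1380, 166, 1765 and 414 genes for high humidity leaves, low humidity leaves, chlorophenol, low against high humidity, leaves against chlorophenol, and the shared set. Between the humidities, the leaf arrays alone gave 69, slide column as a block 88 and array weights 201; the first 2 use fewer arrays and the larger leaf spread. Median scaling, quantile normalization, both other filters, the median over probes, trend with robust moderation, the deposited log2 table and outlier probes kept left all 6 counts within 1.5 times. So did setting single outlier spots missing, the first version used, with 2186, 2017, 2464, 342, 2808 and 930 genes.

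The replicate block gave 2279, 2112, 2529, 370, 2862 and 967 genes in that order and changed no call of a named gene. Leaving out each replicate gave 1936 to 2130 genes for high humidity leaves, 1803 to 2044 for low humidity leaves, 2169 to 2354 for chlorophenol, 223 to 423 between the humidities, 2595 to 2867 for leaves against chlorophenol and 786 to 933 shared. Leaving out genes with disagreeing probes gave 1829 and 1705 genes for the 2 leaf treatments against agar. Of 421 alternative values of the 20 named changes, 419 kept their direction and call, 2 lost the call (both under normexp) and 0 reversed.

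Slide as a block could not be fitted, because each treatment lies on 1 slide. The gene list tests were not run, because the files do not pair locus tags with products. The size of the largest folds depended on the processing. The log2 change of Achl_4300, measured by the 1 probe that passed the filters, ranged from 2.32 to 8.28. Its adjusted p was highest without the filter on dim probes (0.000665, against 2.38e-05 in the main fit), a setting that brings back a tag's dim probes. The log2 change of Achl_3864 on high humidity leaves ranged from 4.26 to 7.54. Nearness to background may limit such folds, but was not tested as the cause of these ranges.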

Other observations

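All tests in this part were chosen after the results were seen.

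Over the 3 treatments compared with agar, 527 genes were lower in all of them and 210 were higher in all. Another 386 genes were higher on both leaf treatments and not called with chlorophenol, and 112 were higher on both leaf treatments and lower with chlorophenol. Of the genes lower on both leaf treatments, 87 were higher with chlorophenol. Opposite calls between high humidity leaves and chlorophenol numbered 161 higher on leaves and 146 lower on leaves. Together they made 307, where independent lists would give 584. Both comparisons use the same agar arrays, which by itself lowers such counts. With the agar arrays split into pairs, opposite calls numbered 112 to 229, against 324 to 382 for independent lists of those lengths. This argues against noise of single shared arrays as the whole cause of the shortfall. A shift common to all agar arrays would enter both comparisons in every split, so it stays open.

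With chlorophenol, the 1497 genes with tags above 1200 and up to 2700, a window picked by eye, had a median log2 change of 0.20, against -0.31 for the other tags. Medians of adjacent blocks of 100 tags correlated at 0.46, against at most 0.37 in 1000 shuffles. On high and low humidity leaves the values of 0.30 and 0.17 lay below the highest of their shuffles, 0.44 and 0.50. Lying below the highest of 1000 shuffles does not show that a trend was absent on leaves. After matching genes on signal level in 5 bins the mean difference was 0.41, with -0.02 in the lowest bin and 0.40 to 0.58 in the others, which argues against level as the whole cause. Between the slide columns of the leaf arrays the same tags differed the opposite way, by -0.16 (SE 0.07, n = 4 each), which argues against a column effect common to both slides, while one of the agar slide alone is confounded with chlorophenol. A dependence of the chlorophenol response on position may be present as a hypothesis; with no coordinates used here, its basis was not tested.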
